A study of Sus scrofa with 9 samples.

How the data were processed

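The series holds 9 porcine microarrays of sorted blood T cells. Per the labels' protocols, mononuclear cells of sows were isolated on Percoll. CD3+CD4+CD8+, CD3+CD4+ and CD3+CD8+ cells were then sorted separately, with 3 arrays per fraction. The labels call these biological replicates. RNA was extracted with Trizol and cleaned on RNeasy columns. Amplification of 25 ng of RNA used the Ovation PicoSL WTA System V2, and the product was labelled with Cy3, per the labels. The antibodies, the purity of the sorted fractions, the number of sows and their age were not given in the sources used here.

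Scanner files and a table of processed values were read. Per the file headers, the scanner files were made with Agilent Feature Extraction 11.0.1.1 and its protocol for arrays of a single colour. Their processed signal is a deposited intensity on a linear scale, already corrected for background and spatial trend and not normalized between arrays. The table of processed values in the series is deposited on a log2 scale, and its program is not given in the sources used here. All 9 of its columns had the same distribution, with a median of 2.60, which is the mark of quantile normalization. Set against the scanner files, larger values in it meant brighter spots, and no centring of genes was seen. The CD3+CD4+CD8+ and CD3+CD4+ columns correlated with their own scanner files at r of 0.994 or more. The 3 CD3+CD8+ columns held the values of each other's arrays, since columns 1, 2 and 3 followed scanner files 3, 1 and 2. This exchange lies within a fraction and leaves the comparisons without a block as they are. The fits with a replicate block depend on the numbering. The numbering of the scanner files was used, and which of them is right is not given in the sources used here.

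The measure used was log2 of the processed signal minus the array's 75th percentile over all probes that are not controls. Control spots and spots marked as non-uniform or as population outliers were left out, which was 1 to 12 spots per array. Spots of a probe were averaged. No spot was saturated. A probe was tested if it was well above background on all 3 arrays of at least 1 fraction and had at least 2 values per fraction. That left 16024 of 43603 probes. Between 32.6% and 53.7% of the probes were well above background per array, and 8 of the 9 arrays had fewer probes above background than not. The percentile was set on all probes before the data were examined and was kept. A percentile over the 11174 probes detected on all 9 arrays was tried as an alternative.

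Probes carry sequence accessions and not gene symbols in these files. A probe was named through the unversioned accession in an annotation of the pig assembly Sscrofa11.1, which gave 6730 probes a name (15.4%) and 3052 genes. Of the tested probes, 3323 (20.7%) were named, for 1507 genes. The other tested probes are unnamed here and not without a gene. Pig genes are given by the annotation's symbols, with SLA- for the genes of the major histocompatibility complex. The files name no genome build, so no coordinates are given.

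Fractions were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a variance trend, two-sided tests and Benjamini-Hochberg adjustment over all tested probes at 0.05. All 9 arrays entered one fit without a block. The stated design sets CD3+CD4+CD8+ against each other fraction. CD3+CD4+ against CD3+CD8+ was added as a reference. A moderated F test covered the 3 fractions together. Adjusted p-values below are from limma unless another test is named, and n = 3 arrays per fraction throughout. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

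Gene lists from textbook knowledge of T cells and other blood cells, 27 in number, were fixed before the data were examined, as were the fits, the filter and all alternatives except those named below as added. A list with at least 3 tested genes, each gene by its probe with the highest mean, was tested with limma's camera at a preset correlation of 0.01, adjusted over the 16 lists tested. Camera with a correlation estimated per list and fry were alternatives. Of the 161 list genes named on the array, 56 were not tested, and 27 were not well above background on any array.

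The genes named were set by a rule. It took the sorting markers, and per comparison up to 10 called genes with the largest rise and 10 with the largest fall whose arrays did not overlap between fractions. From each list described, it took up to 4 called members, or the member with the smallest p where none was called. Probes that set CD3+CD4+CD8+ apart from both other fractions were named likewise. Where several called probes carried one gene, the one with the highest mean was used, and other probes of the gene are counted beside it. Any other gene or probe named was chosen after its values were seen. For a probe not well above background on any array of a fraction only a bound is given. It sets the mean of the brighter fraction against the mean, over arrays of the dimmer one, of the higher of the lowest signal among probes well above background and the probe's own signal.

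The pairing of the arrays and their slides were checked. The labels name no animal. The names of the scanner files carry one common identifier per replicate number in all 3 fractions. On that basis arrays with the same number were taken to come from one animal, but only the fits with a replicate block use this. The main fit, with its p-values and list tests, treats the arrays as independent. The deviations of arrays from their fraction means correlated at a mean r of 0.257 between arrays of one number (range -0.067 to 0.647, 7 of 9 pairs above 0.1). For arrays of different numbers the mean was -0.131, and 7 of 9 arrays correlated best with an array of their own number. Between CD3+CD4+CD8+ arrays 1, 2 and 3 and CD3+CD8+ arrays the values were 0.27, 0.33 and 0.33, but -0.27, -0.19 and -0.30 in the numbering of the processed table. Between CD3+CD4+ and CD3+CD8+ arrays they were -0.03, 0.14 and 0.39, against -0.11, 0.13 and -0.31. These few pairs argue against the numbering of the processed table. The unblocked fit was fixed as the main one, and the fit with the number as a block is given beside a result where it changed a call or moved a count by over 1.5 times. Slides coincided with scans. Slide 1 held CD3+CD4+CD8+ array 1 alone, and slides 2 and 3 held 4 arrays each, with all 3 fractions on both.

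The scripts were tested on simulated data built from these arrays for CD3+CD4+CD8+ against CD3+CD4+. In 10 simulations over 16024 probes with 200 changed, 0.2% of probes changed by 1 on the log2 scale were recovered, 25.2% at 2, 58.6% at 3 and 79.4% at 4. Of all calls, 2.85% were false, and no probe was called without an effect. The simulated arrays and probes varied independently, whereas the deviations of the real arrays correlate. These values therefore do not measure the share of false calls in the real data. A list shifted by 1 among 1507 genes, that of MHC class II, was found in 95% of 20 simulations. Its genes varied independently there, whereas their estimated correlation in the real data was 0.54. The 95% is therefore not the power of the list test in these data. The number of arrays limits the precision.

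Alternatives were another background correction, other scalings, the processed table, other filters, marked spots kept, only the compared fractions in the fit, replicate and slide blocks, other variance models, array weights, a minimum fold, each array left out in turn and, for genes and lists, the mean over a gene's probes. The remaining alternatives were added after the data were seen. Normexp on the median signal replaced the planned form on the mean signal, which the files do not hold, and the replicate block was also run with the CD3+CD8+ arrays numbered as in the processed table.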

Results

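Transcripts were measured in 3 sorted fractions of T cells from the blood of sows, on 9 microarrays. The fractions were CD3+CD4+CD8+ cells, called DP here, CD3+CD4+ cells, called the CD4 fraction, and CD3+CD8+ cells, called the CD8 fraction. In pigs, T cells that carry both CD4 and CD8 are common in blood. Each fraction had 3 arrays (n = 3). The 75th percentile of the signal, from which each array was scaled, was 39.7, 42.5 and 19.0 on the DP arrays, 84.1, 15.2 and 28.8 on the CD4 arrays and 18.4, 24.3 and 29.7 on the CD8 arrays. Probes well above background made up 38.1% to 45.9% on the DP arrays, 32.6% to 53.7% on the CD4 arrays and 33.9% to 45.5% on the CD8 arrays. The gates of the CD4 and CD8 fractions are named in the labels only by the markers they carry.

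The sorting markers were read first, as a check of the sort. CD4, the coreceptor of helper T cells, stood at 2.14 ± 0.91 in DP, 1.92 ± 0.44 in the CD4 fraction and -2.04 ± 1.24 in the CD8 fraction (log2 relative to the 75th percentile, mean ± SD, n = 3). In the CD8 fraction it was well above background on 1 of 3 arrays. CD8A, the alpha chain of the coreceptor of cytotoxic T cells, stood at 3.47 ± 0.76 in DP, 0.27 ± 0.67 in the CD4 fraction and 5.35 ± 0.57 in the CD8 fraction, and was well above background on all 9 arrays. DP exceeded the CD8 fraction 18.1-fold in CD4 (log2 4.17, SE 0.64, limma adjusted p = 0.0208). It exceeded the CD4 fraction 9.18-fold in CD8A (log2 3.20, SE 0.49, adjusted p = 0.0179, 1 of 2 probes called). The difference in CD8A between DP and the CD8 fraction was -1.88 (SE 0.49) and did not pass (adjusted p = 0.218). CD4 differed by 0.22 (SE 0.64) between DP and the CD4 fraction and did not pass. None of CD3D, CD3E and CD3G, chains of the T cell receptor complex, was called in any comparison. CD8B had no named probe and was not analysed here.

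**Figure D1:**
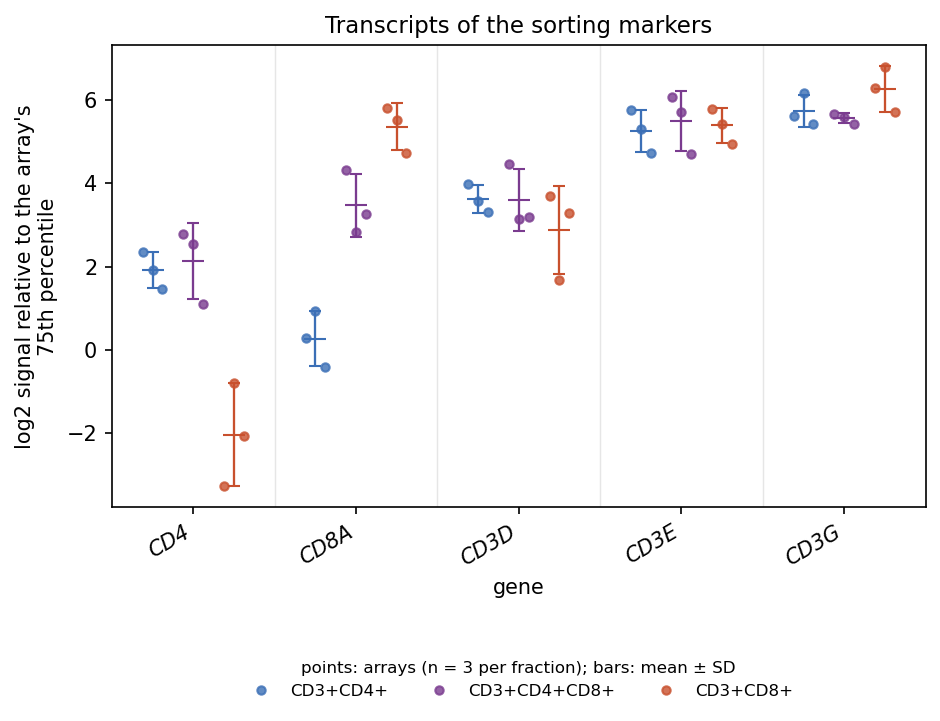
Transcripts of the sorting markers, as log2 signal relative to the 75th percentile of the array. Points are arrays (n = 3 per fraction) and bars are mean ± SD; CD4 averaged 2.14 in the CD3+CD4+CD8+, 1.92 in the CD3+CD4+ and -2.04 in the CD3+CD8+ fraction, and CD8A averaged 3.47, 0.27 and 5.35.

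The first stated comparison set DP against the CD4 fraction. Genes of effector and cytotoxic T cells and of MHC class II were higher in DP. ADGRG1, an adhesion receptor found on cytotoxic lymphocytes, was 99.4-fold higher (log2 6.64, SE 0.60, n = 3 per fraction, limma adjusted p = 0.000966). KLRK1, an activating receptor of natural killer and cytotoxic T cells, was 36.9-fold higher (5.21, SE 0.63), and S1PR5, a sphingosine phosphate receptor of effector lymphocytes, was 29.0-fold higher (4.86, SE 0.69). The chemokine gene CCL5 was 19.7-fold higher (4.30, SE 0.72, 1 of 2 probes called, both with the replicate block) and IFNG, which encodes interferon gamma, was 19.6-fold higher (4.29, SE 0.52). ANGPT2, the gene of the vessel factor angiopoietin 2, was the one named gene called lower in DP without a block, by at least 4.78-fold (adjusted p = 0.0251), and it was not well above background on any DP array.

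Other called genes were LGALS1, which encodes galectin 1 (log2 2.90, SE 0.47, 1 of 2 probes called), and ITGB1, the integrin beta 1 chain (2.97, SE 0.54, adjusted p = 0.0432). For ITGB1, 1 of 6 probes was called, and its brightest probe gave 2.73 (adjusted p = 0.0767). With the replicate block all 6 probes passed. FCGR3A, FGL2 and SLA-DQA1 had called probes beside others that did not pass. In the CD4 fraction KLRK1 and IFNG were well above background on 1 of 3 arrays, and ADGRG1, S1PR5, CCL5 and LGALS1 on 2 of 3.

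Of the 16 lists tested, 6 were higher and 1 was lower in DP than in the CD4 fraction. The MHC class II list, genes that present peptides to helper T cells, had 8 members tested. Of these 2 were higher in DP, none was lower and 6 did not pass, with 7 higher when adjusted over the list alone (median 2.18, camera adjusted p = 5.8e-15). SLA-DQB1 was 7.98-fold higher (log2 3.00, SE 0.53, adjusted p = 0.0338, 2 of 4 probes called) and SLA-DRA was 7.18-fold higher (2.84, SE 0.45, adjusted p = 0.0202, 6 of 7 probes called). SLA-DRB1 gave 3.00 (adjusted p = 0.0509) and passed with the replicate block (adjusted p = 0.00356), which called 5 of the 8. Beside this list, the B cell gene CD79A differed by -0.22 (SE 0.60), and CD86, a costimulatory molecule of antigen-presenting cells, by 2.68 (adjusted p = 0.168). The list of monocytes and granulocytes did not pass (camera adjusted p = 0.383) but passed with a slide block (adjusted p = 0.0188).

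The list of chemokines and trafficking receptors had 10 members tested. CCL5 and S1PR5 were higher, 8 did not pass, and 6 were higher when adjusted over the list alone (median 2.37, or 2.00 with members below background in a whole fraction at their bounds, camera adjusted p = 1.3e-12). The replicate block called 5. The effector memory list had 11 members tested, all with positive differences. CCL5 and LGALS1 were higher, 9 did not pass, and 6 were higher when adjusted over the list alone (median 1.72, camera adjusted p = 7.7e-11). The replicate block called 4. In the type 1 helper list of 6 tested genes IFNG was higher, 5 did not pass, and 3 were higher when adjusted over the list alone (median 2.09, or 1.91 with members at their bounds likewise, camera adjusted p = 1.7e-06). In the cytotoxic effector list of 8 tested genes KLRK1 was higher, 7 did not pass, and 4 were higher when adjusted over the list alone (median 1.65, camera adjusted p = 1.7e-06). GZMH, which encodes a granzyme, gave 2.53 (adjusted p = 0.147). The replicate block called 2 in each of these last lists.

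With an estimated correlation these 5 lists held their calls, at adjusted p = 0.0317 for MHC class II, 0.027 for chemokines, type 1 helper and cytotoxic effector genes, and 0.0456 for effector memory. With both an estimated correlation and the replicate block, type 1 helper and cytotoxic effector genes did not pass (adjusted p = 0.0658 for both). Within slide 2 and slide 3 the median differences were 2.14 and 2.04 for MHC class II, 2.15 and 2.02 for chemokines, 1.66 and 0.91 for effector memory, 1.57 and 2.18 for type 1 helper and 1.09 and 0.99 for cytotoxic effector genes.

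Weaker calls were those of the helper lineage and of naive and central memory cells. None of the 5 tested genes of the helper lineage was called, nor was any when adjusted over the list alone. All differences were positive (median 0.41, camera adjusted p = 0.0347; adjusted p = 0.18 with an estimated correlation and 0.0581 with a slide block). ICOS, a costimulatory receptor, gave 1.31 (SE 0.52, adjusted p = 0.767). None of the 7 tested genes of naive and central memory cells was called. When adjusted over the list alone 3 were lower in DP (median -0.48, mean -0.62, camera adjusted p = 0.00347; adjusted p = 0.0728 with an estimated correlation). Among them CCR7, the homing receptor of naive cells, gave -1.48 (adjusted p = 0.14) and LEF1, a transcription factor of naive T cells, gave -1.45 (adjusted p = 0.147). Within slides 2 and 3 the medians were 0.83 and -0.05 for the helper lineage and -0.47 and -0.92 for naive and central memory genes.

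In all, 47 probes differed between DP and the CD4 fraction, 36 higher and 11 lower in DP. They included 14 named genes, of which 13 were higher and 1 was lower, and with the replicate block 34, of which 28 were higher and 6 were lower. At an unadjusted p under 0.05 there were 775 probes, and 1095 with the replicate block, where chance would give 801, and the fractions did not overlap for 10.1% of probes where chance gives 10%. With the replicate block 144 probes passed (115 higher, 29 lower), among them all 47. With the CD8 arrays numbered as in the processed table, the block gave 30. All 47 kept their direction within slide 2 and within slide 3, with median fitted sizes of 3.07 and 3.45 beside 3.57 over all arrays, but they were chosen on these arrays, from which a shared direction largely follows. With slide as a block, which takes DP array 1 out of the comparison because it was alone on its slide, 2 probes passed. Without DP array 1 there were likewise 2, without CD4 array 2 there were 22 and without CD4 array 3 there were 13.

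**Figure D2:**
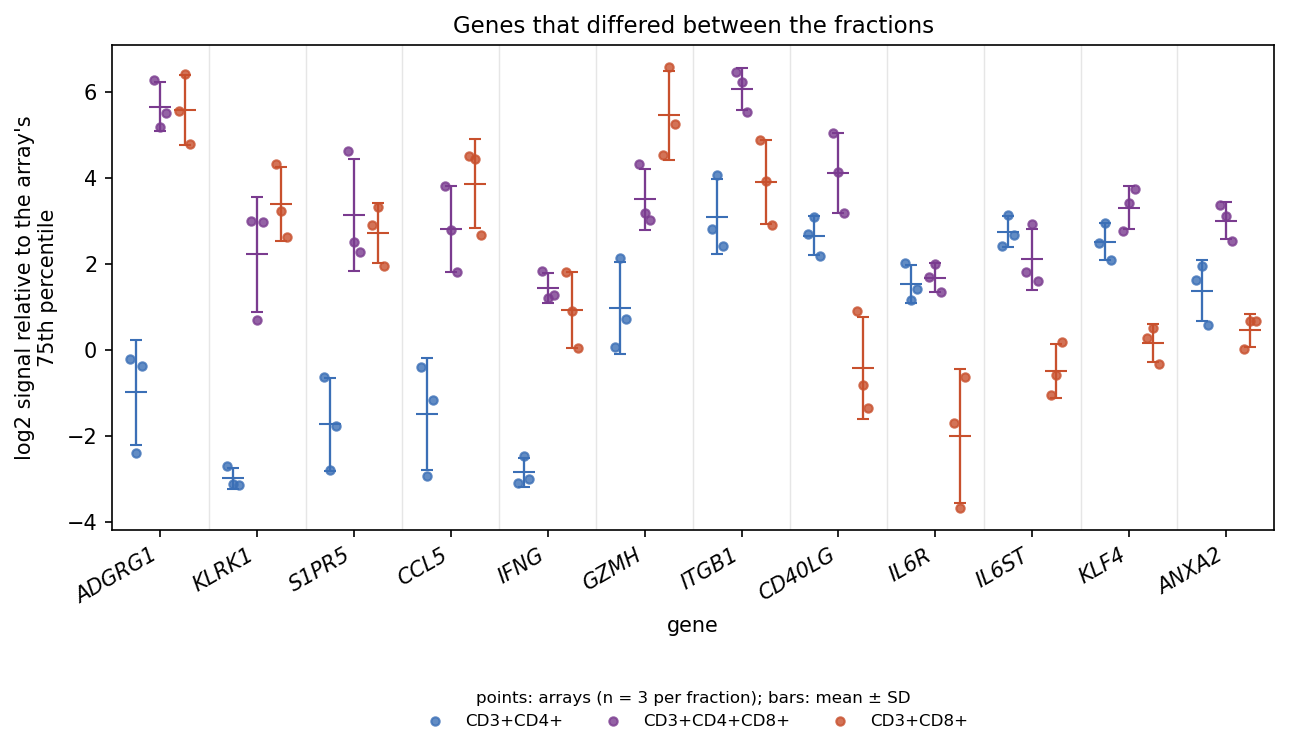
Genes that differed between the fractions, as log2 signal relative to the 75th percentile of the array. Points are arrays (n = 3 per fraction) and bars are mean ± SD; each gene is shown by its brightest probe, except ITGB1 and ANXA2, which are shown by their called probe. ADGRG1 was 99.4-fold higher in CD3+CD4+CD8+ than in CD3+CD4+, and CD40LG 23.3-fold higher in CD3+CD4+CD8+ than in CD3+CD8+.

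**Figure D3:**
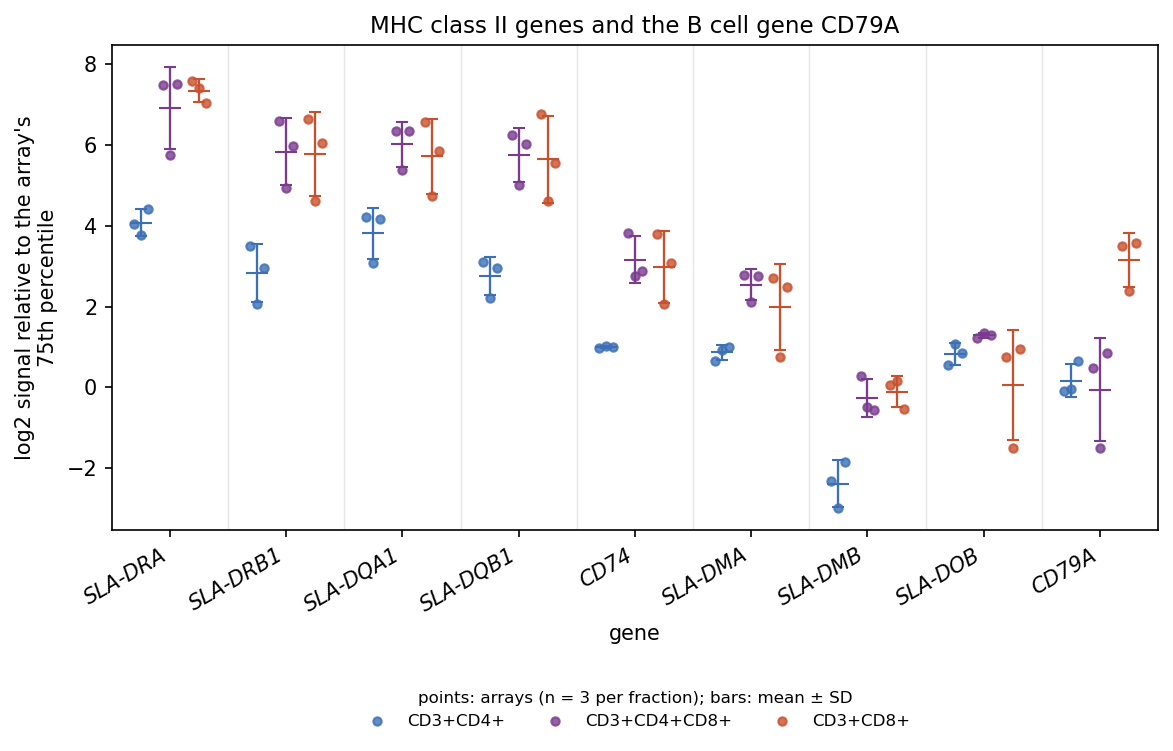
MHC class II genes and CD79A in the 3 fractions, as log2 signal relative to the 75th percentile of the array. Points are arrays (n = 3 per fraction) and bars are mean ± SD; SLA-DRA averaged 6.91 in the CD3+CD4+CD8+, 4.07 in the CD3+CD4+ and 7.34 in the CD3+CD8+ fraction, and CD79A averaged -0.05, 0.17 and 3.15.

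The second stated comparison set DP against the CD8 fraction. Helper T cell genes and chains of the interleukin 6 receptor were higher in DP. CD40LG, the ligand through which helper T cells activate B cells, was 23.3-fold higher (log2 4.54, SE 0.61, n = 3 per fraction, limma adjusted p = 0.00927). IL6R, a chain of the interleukin 6 receptor, was 12.9-fold higher (3.69, SE 0.65, 2 of 3 probes called) and IL6ST, its signalling chain, was 6.04-fold higher (2.59, SE 0.48, 1 of 2 probes called). KLF4, a transcription factor, was 8.84-fold higher (3.14, SE 0.43, 4 of 7 probes called). ANXA2, annexin A2, was 5.85-fold higher by 1 of 3 probes (2.55, SE 0.46, adjusted p = 0.045), and its brightest probe gave 2.05 (adjusted p = 0.175).

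Among the genes lower in DP than in the CD8 fraction, CD79A, a chain of the B cell receptor complex, was 9.22-fold lower (log2 -3.20, SE 0.60, adjusted p = 0.0452). It was well above background on all 9 arrays. SCD, which encodes a desaturase of fatty acid synthesis, was 9.02-fold lower (-3.17, SE 0.53, 2 of 6 probes called). The receptor gene CD96 was at least 14.5-fold lower, LIMA1 at least 7.47-fold, BEX1 at least 6.55-fold, LCORL at least 4.94-fold, ANGPT2 at least 4.77-fold and the cadherin gene CDH1 at least 2.78-fold. None of these 6 was well above background on any DP array. LIMA1 passed at an adjusted p of 0.0452 and did not pass with the replicate block (adjusted p = 0.0577). IL6R was well above background on 1 of 3 arrays of the CD8 fraction, and IL6ST on 2 of 3.

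Of the 16 lists tested, 5 were higher in DP than in the CD8 fraction and none was lower. The helper lineage list had 5 members tested. CD4 and CD40LG were higher, 3 did not pass, and all 5 were higher when adjusted over the list alone (median 2.37, camera adjusted p = 3.8e-10). CD4 is a sorting marker, so its rise follows from the sort, and the list was not tested without it. The list held its call at adjusted p = 0.0175 with an estimated correlation, and its medians within slides 2 and 3 were 2.32 and 1.99. GATA3, a transcription factor of helper cells, gave 2.37 (adjusted p = 0.226).

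The other 4 calls were lost with an estimated correlation. In the list of cytokine receptors IL6R and IL6ST were higher, 7 of 9 did not pass, and 4 were higher when adjusted over the list alone (median 0.48, camera adjusted p = 0.00015; adjusted p = 0.145 with an estimated correlation). None of the 11 effector memory genes was called. When adjusted over the list alone 3 were higher (median 0.87, camera adjusted p = 0.00316; adjusted p = 0.464 with an estimated correlation). None of the 6 type 1 helper genes was called, and 1 was higher when adjusted over the list alone (median 0.89, camera adjusted p = 0.0129; adjusted p = 0.236 with an estimated correlation). IL18R1, a chain of the interleukin 18 receptor, gave 2.63 (adjusted p = 0.398). None of the 8 immediate early and heat shock genes, which respond to handling and stress, was called. When adjusted over the list alone 1 was higher (median 0.48, camera adjusted p = 0.0304; adjusted p = 0.464 with an estimated correlation). HSPH1, a heat shock protein gene, gave 1.31 (adjusted p = 0.311). Within slides 2 and 3 the medians were 1.23 and 0.83 for cytokine receptors, 0.78 and 0.74 for effector memory, 0.87 and 1.86 for type 1 helper and 0.44 and 0.71 for immediate early genes.

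Of the 7 lists that differed between DP and the CD4 fraction, 4 did not pass between DP and the CD8 fraction. These were MHC class II, cytotoxic effector, chemokine (camera adjusted p = 0.208) and naive and central memory genes (0.425). The 8 MHC class II genes had a median difference of 0.15 (camera adjusted p = 0.618), with SLA-DRA at -0.43 (SE 0.45). The 8 cytotoxic effector genes had a median of -0.71 (camera adjusted p = 0.287), with KLRK1 at -1.17 (SE 0.63). ADGRG1 differed by 0.07 (SE 0.60).

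In all, 50 probes differed between DP and the CD8 fraction, 21 higher and 29 lower in DP, with 6 named genes higher and 8 lower. At an unadjusted p under 0.05 there were 1045 probes, and 1555 with the replicate block, where chance would give 801, and the fractions did not overlap for 9.77% of probes where chance gives 10%. With the replicate block 83 probes passed (40 higher, 43 lower), among them 49 of the 50. With the numbering of the processed table the block gave 21. All 50 kept their direction within slide 2 and within slide 3, with median sizes of 3.84 and 3.26 beside 3.73 over all arrays, which likewise largely follows from their choice on these arrays. With slide as a block 2 probes passed. Without DP array 1 there was 1 probe, without DP array 2 there were 9, without CD4 array 2 there were 16 and without CD4 array 3 there were 25. Without CD8 arrays 1, 2 and 3 in turn there were 21, 3 and 18.

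The third pair, the CD4 against the CD8 fraction, served as a reference for the other comparisons. Genes of cytotoxic cells were lower in the CD4 fraction. ADGRG1 was 94.7-fold lower (log2 -6.57, SE 0.60, n = 3 per fraction, limma adjusted p = 0.000985) and KLRK1 was 83.0-fold lower (-6.38, SE 0.63). CCL5 was 41.1-fold lower (-5.36, SE 0.72), CD8A 33.8-fold (-5.08, SE 0.49), the granzyme gene GZMH 22.2-fold (-4.47, SE 0.62, 1 of 2 probes called), S1PR5 21.7-fold (-4.44, SE 0.69) and IFNG 13.6-fold (-3.77, SE 0.52). CD96 was at least 14.9-fold lower, UCHL1, a deubiquitinating enzyme gene, at least 7.84-fold and MGST1, a glutathione transferase gene, at least 5.53-fold by 1 of 6 probes. As in the first comparison, KLRK1 and IFNG were well above background on 1 of 3 arrays of the CD4 fraction, and ADGRG1, CCL5 and S1PR5 on 2 of 3, so these folds rest partly on signals near background.

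Higher in the CD4 fraction were CD4 (log2 3.96, SE 0.64, 15.5-fold), IL6R (3.54, SE 0.65, 11.6-fold, 2 of 3 probes called), IL6ST (3.23, SE 0.48, 9.39-fold, 1 of 2 probes called) and KLF4 (2.35, SE 0.43, 5.10-fold, 1 of 7 probes called). In the CD8 fraction CD4 and IL6R were well above background on 1 of 3 arrays and IL6ST on 2 of 3. STMN1, a regulator of microtubules, was at least 3.87-fold higher by 1 of 5 probes, and FST, which encodes follistatin, at least 2.75-fold by 1 of 2 probes. The brightest STMN1 probe gave 1.69 (adjusted p = 0.102) and passed with the replicate block (adjusted p = 0.0385). CD40LG gave 3.07 (SE 0.61, adjusted p = 0.0505) and passed with the replicate block (adjusted p = 0.00746).

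Of the 16 lists tested, 2 were higher and 6 were lower in the CD4 than in the CD8 fraction. In the helper lineage list of 5 tested genes CD4 was higher, 4 did not pass, and 4 were higher when adjusted over the list alone (median 1.99, camera adjusted p = 1.1e-06). The call of CD4 follows from the sort, and here too the list was not tested without CD4. In the cytotoxic effector list of 8 tested genes GZMH and KLRK1 were lower, 6 did not pass, and 3 were lower when adjusted over the list alone (median -2.34, camera adjusted p = 2.6e-07). The replicate block called 4 of them. These lists held their calls with an estimated correlation (adjusted p = 0.0329 and 0.0218) but not with that and the replicate block (adjusted p = 0.0604 and 0.0617).

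The other 6 calls were lost with an estimated correlation. In the MHC class II list of 8 tested genes SLA-DRA (log2 -3.27, SE 0.45, 6 of 7 probes called), SLA-DRB1 (-2.94, SE 0.57, 1 of 4) and SLA-DQB1 (-2.88, SE 0.53, 3 of 4) were lower in the CD4 fraction and 5 did not pass. SLA-DQA1 was called by probes other than the one in the list. When adjusted over the list alone 6 were lower (median -2.13, camera adjusted p = 5.0e-11; adjusted p = 0.0521 with an estimated correlation). Beside this list CD79A gave -2.98 (SE 0.60, adjusted p = 0.0561), which passed with the replicate block (adjusted p = 0.00949). In the list of chemokines and trafficking receptors CCL5 and S1PR5 were lower, 8 of 10 did not pass, and 5 were lower when adjusted over the list alone (median -1.40, or -0.80 with members below background in a whole fraction at their bounds, camera adjusted p = 2.6e-07; adjusted p = 0.0521 with an estimated correlation). In the list of cytokine receptors IL6R and IL6ST were higher, 7 of 9 did not pass, and 3 were higher when adjusted over the list alone (median 0.80, camera adjusted p = 3.9e-05; adjusted p = 0.0521 with an estimated correlation).

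None of the 3 tested natural killer cell genes was called between the CD4 and the CD8 fraction, and 2 were lower when adjusted over the list alone (median -2.09, camera adjusted p = 0.00408; adjusted p = 0.0521 with an estimated correlation). Among them FCGR3A, an Fc receptor gene, gave -2.09 (adjusted p = 0.206) and passed with the replicate block (adjusted p = 0.00746). In the effector memory list of 11 tested genes CCL5 was lower, 10 did not pass, and 2 were lower when adjusted over the list alone (median -0.77, camera adjusted p = 0.00269; adjusted p = 0.266 with an estimated correlation). In the type 1 helper list of 6 tested genes IFNG was lower, 5 did not pass, and 2 were lower when adjusted over the list alone (median -0.29, camera adjusted p = 0.0474; adjusted p = 0.207 with an estimated correlation and 0.0565 with the replicate block). Within slides 2 and 3 the medians were 2.22 and 1.87 for the helper lineage, -2.22 and -1.50 for cytotoxic effector, -2.83 and -1.88 for MHC class II, -1.53 and -0.83 for chemokines and 1.47 and 0.52 for cytokine receptors. They were -2.08 and -1.43 for natural killer cell genes, -1.10 and 0.12 for effector memory and -0.58 and -0.07 for type 1 helper genes.

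In all, 70 probes differed between the CD4 and the CD8 fraction, 18 higher and 52 lower in the CD4 fraction, with 6 named genes higher and 14 lower, or 8 and 22 with the replicate block. At an unadjusted p under 0.05 there were 727 probes, and 1139 with the replicate block, where chance would give 801, and the fractions did not overlap for 8.01% of probes where chance gives 10%. With the replicate block 110 probes passed (33 higher, 77 lower), among them 69 of the 70, and the numbering of the processed table gave 50. All 70 kept their direction within slide 2 and within slide 3, with median sizes of 3.78 and 3.41 beside 3.77 over all arrays, which again largely follows from their choice. With slide as a block 38 passed. Without CD4 array 1 there were 41 probes, without CD4 array 2 there were 40, and without CD8 arrays 1, 2 and 3 in turn there were 41, 31 and 46. The F test over the 3 fractions called 98 probes, 212 with the replicate block and 70 with that block in the numbering of the processed table. It called 32 with slide as a block. It called 53 without DP array 1, 63 without DP array 2, 62 without CD4 array 2, 58 without CD4 array 3 and 52 without CD8 array 2.

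No probe was higher in DP than in both other fractions, and 5 were lower. The named one was ANGPT2, at least 4.78-fold lower than in the CD4 and 4.77-fold lower than in the CD8 fraction. Among the unnamed, A_72_P086236 was at least 3.55-fold and 11.9-fold lower, and A_72_P408628 at least 8.52-fold and 5.96-fold lower. Of the 5, 4 were not well above background on any DP array, and the other was on 1. Both comparisons share the DP arrays. In 50 simulations of unchanged fractions the count was 0, and independent lists would share 0.0472 higher and 0.0199 lower probes. Neither decides on the 5, since without an effect no probe was called even in a single comparison, and independent lists leave out the shared arrays. At an unadjusted p under 0.05, 300 probes moved the same way in both comparisons where simulation gave 167 on average and at most 196. The simulated comparisons shared the DP arrays in the same way, so sharing them did not give this count where probes vary independently. Deviations of a shared DP array that run through many probes were not simulated, so whether they account for the excess stays open. The simulation let arrays and probes vary independently, without the pairing by replicate number, and was not run with the replicate block. Its range is therefore not a full measure of chance here. With the replicate block 13 probes passed, 4 higher and 9 lower, and 3 passed with the numbering of the processed table. These added BEX1 among the lower and 2 probes of ITGB1 among the higher. With slide as a block there were none. The count of 5 was 0 without DP array 1 and without CD4 array 3. It was 2 without DP array 2, 2 without CD4 array 1, 1 without CD4 array 2, and 3, 2 and 2 without CD8 arrays 1, 2 and 3.

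The place of DP between the other fractions was read on the 70 probes that differed between these. The DP mean lay nearer the CD4 fraction for 28 of them (40.0%), and the share was 40.0%, 44.3% and 42.9% on the single DP arrays. By the DP mean, all 18 probes higher in the CD4 fraction lay nearer the CD4 fraction, among them CD4, IL6R and IL6ST. On the single DP arrays 100%, 94.4% and 83.3% of them did, and with the replicate block 29 of 33 did. Of the 52 probes higher in the CD8 fraction, 10 (19.2%) lay nearer the CD4 fraction, and 19.2%, 26.9% and 28.8% on the single DP arrays. By the DP mean the others, among them ADGRG1, KLRK1 and SLA-DRA, lay nearer the CD8 fraction. Probes of the sorting markers CD4 and CD8A are among the 70. Their place follows at least partly from the sort, and the position was not read without them. On a scale from 0 at the CD4 mean to 1 at the CD8 mean, the median DP position was 0.141 for the first set and 0.901 for the second. The dimmer end of this scale was not well above background on any array for 11 of the 18 and 19 of the 52 probes, where the position is not exact. It was above background on all 3 arrays for 1 and 18 of them, of which the 1 lay nearer the CD4 fraction and the 18 nearer the CD8 fraction (median 0.915). Apart from CD8A and GZMH, the named probes among these 18 were all of MHC class II genes, namely SLA-DRA, SLA-DRB1, SLA-DQA1 and SLA-DQB1. Most of these genes had several probes there, so the named part of this reading rests largely on a single gene family. The share of 40.0% was 24.4% without CD4 array 1 and 12.9% without CD8 array 2. It was 0 over the 12 probes called when only probes above background on all arrays were kept. This share also follows the mix of calls, since the probes higher in the CD4 fraction fell from 18 to 6, 3 and 0 in these settings. Of them 5 of 6 and 3 of 3 lay nearer the CD4 fraction. Of the probes higher in the CD8 fraction, 5 of 35 (14.3%), 1 of 28 (3.57%) and 0 of 12 did. The probes are not independent, and no test was made.

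**Figure D4:**
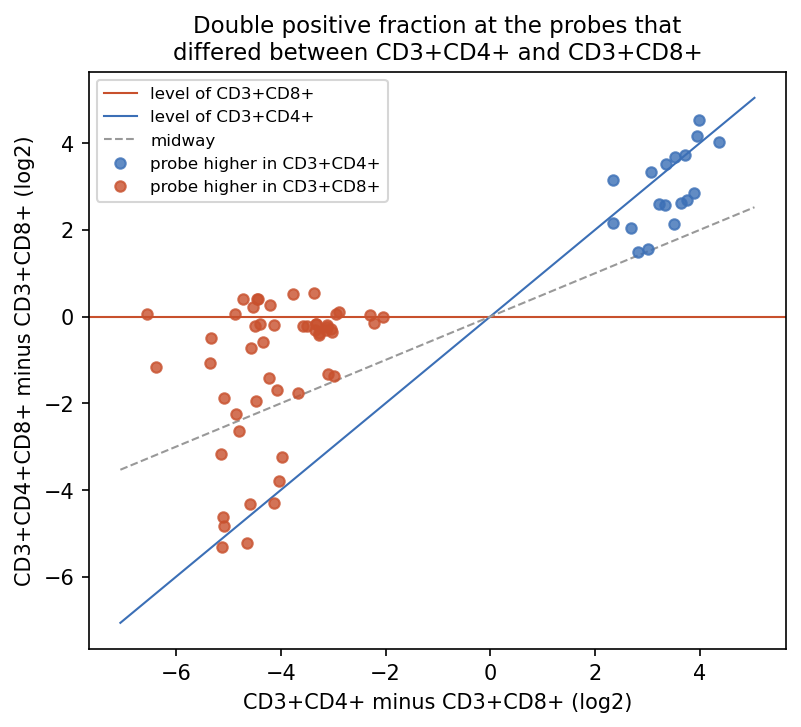
CD3+CD4+CD8+ minus CD3+CD8+ (vertical, log2) against CD3+CD4+ minus CD3+CD8+ (horizontal, log2) for the 70 probes called between CD3+CD4+ and CD3+CD8+. Each point is a probe. The horizontal line marks the level of CD3+CD8+, the solid diagonal that of CD3+CD4+ and the dashed line midway. On a scale from the CD3+CD4+ mean (0) to the CD3+CD8+ mean (1), the median position was 0.141 for the 18 probes higher in CD3+CD4+ and 0.901 for the 52 higher in CD3+CD8+. For 11 and 19 of these the dimmer of both fractions was not well above background on any array.

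Markers of other cells and of general states were read in all 3 comparisons. None of the lists of T cell receptor signalling, interferon response, glycolysis and platelets passed in any comparison, nor did the sorting markers as a list or the monocyte and granulocyte list. Their camera adjusted p-values, for DP against CD4, DP against CD8 and CD4 against CD8, were 0.642, 0.755 and 0.687 for T cell receptor signalling. The interferon response gave 0.991, 0.694 and 0.666, glycolysis 0.991, 0.692 and 0.631, platelets 0.768, 0.755 and 0.568, the sorting markers 0.133, 0.755 and 0.687, and monocytes and granulocytes 0.383, 0.692 and 0.0722. Median, mean and test differed in sign for cytokine receptors in DP against CD4 (median 0.15, mean 0.13, test lower). They did so for the interferon response in DP against CD4 (-0.04, 0.04, higher) and CD4 against CD8 (-0.05, 0.16, higher) and for glycolysis in CD4 against CD8 (-0.06, 0.10, higher). With a slide block the monocyte and granulocyte list passed in DP against CD4 (adjusted p = 0.0188) and in CD4 against CD8 (adjusted p = 0.0133).

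The natural killer cell list did not pass in DP against CD4 (camera adjusted p = 0.0984, and 0.0113 with a slide block) or DP against CD8 (0.618). FCGR3A was 2.81 higher in DP than in the CD4 fraction by its brightest probe (adjusted p = 0.0509), which passed with the replicate block (adjusted p = 0.00356). FCER1G, an Fc receptor chain, gave -2.33 between DP and the CD8 fraction (adjusted p = 0.518). Naive and central memory genes did not pass in CD4 against CD8 (camera adjusted p = 0.0593, and 0.0207 with a slide block). Immediate early genes did not pass in DP against CD4 (0.642) or CD4 against CD8 (0.0703, and 0.0318 with a slide block). Cytokine receptors did not pass in DP against CD4 (0.991).

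Lists with fewer than 3 tested genes had no list test. Both tested genes of the cytotoxic lineage, CD8A and KLRK1, were higher in DP than in the CD4 fraction, and lower in the CD4 than in the CD8 fraction. Neither was called between DP and the CD8 fraction. CD8A is a sorting marker, so its calls follow from the sort. CD79A, the B cell gene tested, was lower in DP than in the CD8 fraction. No call was made in any comparison for GATA3 and IL5 of the type 2 helper list, IL10 of the regulatory list, ICOS of the follicular list, BIRC5 of the cell cycle list, ID3 and IL18R1 of the gamma delta list or CD1.1 of the dendritic cell list. No gene of the type 17 helper, inhibitory receptor and erythroid lists was tested, and these were not analysed here.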

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

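The normexp correction and the replicate block numbered as in the processed table were tests chosen after the data were seen, and the others were planned. Leaving out 1 array in turn gave 2 to 55 probes for DP against CD4, 1 to 51 for DP against CD8, 31 to 81 for CD4 against CD8 and 52 to 114 in the F test. It gave 0 to 5 probes apart from both fractions, 12.9% to 44.9% for the position, and 2 to 6 lists for DP against CD8. A fraction left with fewer arrays is assumed to vary like the others. No result reversed. In the order DP against CD4, DP against CD8, CD4 against CD8, F test and apart from both, the values reported were 47, 50, 70, 98 and 5, and 40.0% for the position, which also follows the mix of calls. Normexp gave 1, 7, 6, 7 and 0 and 66.7%. Its offset of 50 exceeds the 75th percentile of all arrays but CD4 array 1, which by construction shrinks log2 differences. The share of higher against lower calls moved by over 10 percentage points among the scalings and corrections only there. Without a filter the values were 109, 87, 201 for the F test, 14 apart from both and 42.3%. With probes above background on all arrays, which leaves fewer probes, they were 12, 5, 12, 18 and 0, a position of 0 and 3 lists for DP against CD8. For the scalings the cause was not tested. Scaling on detected probes gave 22 for DP against CD8, the processed table gave 24 and 3 apart from both, and quantile normalization 3 apart from both. Fitting only the compared fractions, with fewer arrays, gave 29 and 22 for the DP comparisons, 1 apart from both and 43.5%. The replicate block gave 144, 83, 110, 212 and 13. The block numbered as in the processed table gave 30, 21, 50, 70 and 3. The replicate block changed no other call of a list at the preset correlation than the one given for type 1 helper genes. Slide as a block gave 2, 2, 38, 32 and 0 and a position of 34.2%, and takes DP array 1 out by construction. Slide and replicate block together gave 81, 99, 169 in the F test, 13 apart from both and 50%. For the variance models the cause was not tested. Without a variance trend 10 probes stood apart from both and the position was 44.9%. Array weights gave 225 for DP against CD4, 233 in the F test and 15 apart from both. An estimated correlation left 1 list for DP against CD8 and 2 for CD4 against CD8, and fry left 1 for DP against CD8. Spots with outlier marks kept, a robust variance prior, a minimum fold and the mean over probes moved none of these results beyond 1.5 times or the spread between arrays. The minimum of 1 on the log2 scale could remove no call between fractions, since the smallest called differences were 2.02, 2.49 and 2.04. Marked spots were few, at 1 to 12 per array, so keeping them could change little.

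All 44 named calls kept their sign in every setting in which they were tested. ADGRG1 in both comparisons with the CD4 fraction and CD8A between the CD4 and CD8 fractions, 3 in number, stayed past the threshold in all settings other than leaving out an array. Leaving out any 1 array kept 8 of the calls. These were ADGRG1 in DP against CD4 and CD8A, ADGRG1, KLRK1, CCL5, GZMH, IFNG and SLA-DRA in CD4 against CD8. No named call between DP and the CD8 fraction was kept without every array, and without DP array 1 all 14 were lost. Of the 1149 values of named genes in the other settings 973 kept their side of the threshold, 155 lost the call and 21 gained one. Over all settings, arrays left out included, 27 values of 7 genes changed sign without a call in either fit, at -0.21 to 0.50. The planned normexp on the mean signal was not run, because the files lack that column, and a robust variance prior was not run for lists. Signals near background limit the rest, since 16024 of 43603 probes were bright enough to be tested.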

Other observations

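The tests of B cells, monocytes and slides were chosen after the results were seen, and the splits of the arrays were planned.

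Genes of other blood cells named here were chosen after their values were seen. CD163, S100A8 and S100A9, genes of monocytes and granulocytes, and NCR1, a natural killer cell gene, were not well above background on any of the 9 arrays. The B cell gene MS4A1 was well above background on 2 DP, 1 CD4 and 2 CD8 arrays, and the monocyte gene CD14 on 2 DP, 2 CD4 and 1 CD8 array. CD79A stood at -0.05 ± 1.27 in DP, 0.17 ± 0.41 in the CD4 fraction and 3.15 ± 0.66 in the CD8 fraction (mean ± SD, n = 3).

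MHC class II genes had a median 2.18 higher in DP than in the CD4 fraction, and these genes are also expressed by B cells, monocytes and activated T cells. B cells, which the gate on CD3 would remove, would bring CD79A, the tested gene of the B cell list. The upper 95% limit of the CD79A difference was 1.08, below the median of MHC class II, which argues against B cells as the whole source. For monocytes, which that gate would remove too, the mean difference of the 5 tested list genes was 0.36, below that median by more than their SD of 1.60. That met the bound set for excluding monocytes, but a single gene of the 5 was above background on all 6 arrays. For that reason, given after the value was seen, the test was held undecided and monocytes stay open.

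MHC class II genes were also higher in the CD8 than in the CD4 fraction, and CD79A moved with them, by 2.98 where MHC class II moved by 2.13. B cells may therefore be a source there, and B cells and T cells of this fraction cannot be told apart on these values. DP cells had MHC class II at a level near the CD8 fraction (median difference 0.15) with CD79A lower by 3.20 on the log2 scale.

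CD79A was 3.09 higher in the CD8 fraction than in the mean of the other fractions. If B cells were the cause, MS4A1 could be higher too. It differed by 0.27, but its 95% interval ran from -2.92 to 3.46 and included the difference of CD79A, so the source stays open. No biological explanation was tested.

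Arrays of one replicate number deviated together, and slides were tested as the reason. Arrays of different numbers on 1 slide had a mean correlation of deviations of -0.19, against 0.18 for arrays of 1 number on different slides. These were 4 and 3 pairs, their ranges overlapped (-0.57 to 0.13 and -0.03 to 0.31), and deviations from a fraction mean sum to 0 within the fraction, which pushes pairs of different numbers down. Slides therefore stay open. Shared animals, the reading taken from the file names, were not tested further.

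Other splits of the arrays were counted. In the F test 2 of 100 drawn splits, the real one included, gave at least the 98 probes of the real split, and the highest other gave 132. This share lies under 0.05, the bound set beforehand, but another split gave more probes than the real one. Among the 36 splits that part every replicate number, 1, the real one, gave as many, and the highest other gave 55. In both sets the tested probes had been filtered with the real fractions, which can favour the real split, so chance is not excluded. Setting the groups to the replicate numbers gave 25 probes. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. DP against CD4 gave 47 probes in the real split and 179 in the highest other, so 2 of 10 gave as many. That split set DP arrays 1 and 2 and CD4 array 1, the arrays with the highest 75th percentiles of the 6, against the rest, and its count points to a structure of the samples. It was singled out after its count was seen, and whether its probes follow signal was not tested. Splits that part all 3 numbers gave 0 besides the real one, and the replicate block gave 144. DP against CD8 gave 50 and the highest other 13, so 1 of 10 gave as many. CD4 against CD8 gave 70 and the highest other 0, likewise 1 of 10.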
